A study of Homo sapiens with 4 samples.

How the data were processed

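ATAC-seq libraries of MCF7-ABER cells treated with a control ASO or an ASO against SUV39H2 were compared through their deposited peak lists, 2 libraries per group. Groups, replicate numbers and batches were taken from the sample labels. Nothing in the labels says that the libraries came from separate cultures. The exact permutation tests on values per library thus measure only the spread between these libraries, which may be technical. The Fisher's exact, Cochran-Mantel-Haenszel and binomial tests take regions as units and measure no spread between libraries.

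Per the submitters' processing notes, the reads were handled with Trimmomatic 0.39, FastQC 0.11.9, Bowtie2 2.4.5, Picard, SAMtools, MACS2 2.2.9.1 and deepTools, on GRCh38.p14 (hg38). Per the file headers, the authors called peaks in each library on its own, without a control library, from BED tags with all duplicates kept at that step. Each tag was moved by -75 bp and extended to 150 bp with no fragment model, which centres the signal on the transposase cut, at a q cutoff of 0.05. Local background was taken over 10000 bp with an effective genome size of 3298430636 bp. Replicates were not pooled. Tag sizes were 82 and 79 bp in batch 1 and 64 bp in both libraries of batch 2, so tag length followed the batch. The pileup at each summit is a coverage signal in tags, as the authors' peak caller wrote it per the file headers. The fold enrichment is the authors' ratio of that pileup to the local background. The −log10 q-value of each peak is also the authors', per the file headers. Peak length is in bp, as deposited. These values belong to single peaks and were used only to describe, rank and filter peaks within a list. A threshold on q in lists of unequal tags and unequal background calls unequal numbers of weak peaks, so presence in one list and absence in another is no measure of how much a site changed.

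Peaks on chromosomes 1 to 22 and X were merged across the 4 libraries where they overlapped by at least 1 bp, and a region was called in a library when a peak of that library overlapped it by at least 1 bp. Peaks on chromosome Y, 2 or 3 per library, were left out. Gained and lost regions were those called in both libraries of one group and in neither of the other. The same counts were made for the other 2 ways to part 4 libraries into pairs, and no p was computed for a single region. Numbers of gained and lost regions in genomic classes, chromosomes and gene lists were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 3 classes, 23 chromosomes or 42 lists, with log2 odds and SE after adding 0.5 to each count. Intervals of shares are exact binomial 95% intervals and cover counting error only. Regions are not independent replicates.

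The gene table used here was RefSeq on GRCh38.p14 with 19970 protein-coding genes. It gives no strand and no exons, so start sites could not be told from the other ends of genes, and a region counted as at a gene end when it lay within 1000 bp of either end. Other regions were inside a gene or between genes by the summit of their strongest peak. A region was assigned to the gene that holds its summit, or to the nearest gene end within 100 kb. The design fixed before the data were examined had named start sites, exons and introns for these steps. Motifs, GC content and repeats need a genome sequence and were not analysed here.

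The 42 gene lists, the tests, the rule for named genes and most of the other settings tried were fixed before the data were examined. The rule takes SUV39H2 and SUV39H1, a fixed panel of 19 breast cancer and cell cycle genes, the 10 gained and 10 lost gene-end regions and the 5 gained and 5 lost regions of any class with the highest weaker percentile, up to 4 members with the most gained and 4 with the most lost regions in lists that passed and in the H3K9, CDK4/6, estrogen, interferon and zinc finger lists, and up to 5 genes with at least 5 gained and no lost regions and 5 with the reverse. The remaining p53 list members, and KIF16B and SARAF, which tied with the last genes of the rule, were named after their values were seen.

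The labels give the batch of each library, and the replicate numbers match the batches, so the numbers pair the libraries across groups. A replicate block was therefore run as a Cochran-Mantel-Haenszel test over the 2 batches of regions called in only one library of a batch. Alternatives were stricter q thresholds, equal numbers of strongest peaks per library, 50% coverage of a region, windows of 250 bp around summits, other distances to genes, autosomes only, and each library left out in turn. The tests of classes, chromosomes and lists at stricter thresholds, at fewer strongest peaks and with other forms of region, and the tests per gene and per window of 5 Mb, were added after seeing the data.

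The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Region building was tested on simulated data for the comparison of the ASO groups over 259568 regions, where 200 of 200 planted gained regions were recovered. Peaks were placed inside regions already apart from each other, so this tests the code only. Other calls were drawn independently in each library, and 14825 regions were gained by chance or planting. That count is no expectation for the data, with 10926 gained, since real calls at a site go together between libraries. For the gene lists, 20 shuffles of 19088 gained and lost regions gave 1 false call over 42 lists each, and a p53 list planted at 83% gained was called in 13 of the 20 shuffles. The shuffles moved regions singly and did not keep neighbouring regions together, so this rate holds for independent regions only.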

Results

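Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in MCF7-ABER cells. MCF7 is an established breast cancer line that expresses the estrogen receptor, and the series was deposited in the context of resistance to CDK4/6 inhibitors and of exon skipping in SUV39H2. SUV39H2 is a histone methyltransferase that trimethylates lysine 9 of histone H3, a mark of heterochromatin. The cells had received an antisense oligonucleotide (ASO) against SUV39H2 or a control ASO (Ctr ASO), with 2 libraries per group, and each group had 1 library in batch 1 and 1 in batch 2. The Ctr ASO libraries held 60784911 and 65661691 tags and gave 155086 and 148507 peaks in the authors' deposited lists. The SUV39H2 ASO libraries held 58902888 and 55478293 tags and gave 155570 and 124219 peaks. The number of peaks averaged 151796 ± 4652 (SD, n = 2) with Ctr ASO and 139894 ± 22169 (SD, n = 2) with SUV39H2 ASO, a difference within the spread between replicates (exact permutation test, two-sided p = 1; 2 against 2 libraries cannot give a p below 0.333). The authors' fold enrichment over local background had a median of 4.26 in each Ctr ASO library, and of 5.20 and 5.37 in the SUV39H2 ASO libraries (exact permutation p = 0.333). Peaks with a −log10 q of at least 10 made up 42.0% and 42.2% of the Ctr ASO lists and 53.7% and 54.8% of the SUV39H2 ASO lists.

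The comparison of the groups asked which sites were called only with the SUV39H2 ASO or only with the control. Merging all peaks gave 274353 regions on chromosomes 1 to 22 and X, of which 69712 (25.4%) were called in all 4 libraries and 143515 (52.3%) in 1 library. A total of 10926 regions were called in both SUV39H2 ASO libraries and in neither Ctr ASO library (gained regions), and 8162 were called in both Ctr ASO libraries and in neither SUV39H2 ASO library (lost regions). Regions were ranked by the weaker of their percentiles of −log10 q, which is not a ranking by fold. The median of this weaker percentile was 32.2 for gained and 20.4 for lost regions, against 66.5 for regions called in all 4 libraries. Their median lengths were 255, 287 and 482 bp. Most gained and lost regions were thus weak and short calls, where a missing call does not show a closed site. The gained region at a gene end that ranked highest lay at TUBD1, which encodes delta-tubulin, on chromosome 17:59859490-59859742. The lost region at a gene end that ranked highest lay at ACTB, the gene of beta-actin, on chromosome 7:5525733-5527169. Their folds, 4.73 and 4.05 at TUBD1 and 2.57 and 2.38 at ACTB, lay below the medians of the lists that held them. Parting the same 4 libraries by batch gave 2423 and 7967 pair-specific regions, and the crossed pairing gave 6553 and 2832. The geometric mean of the counts was thus 9443 for the treatment against 4394 for batch and 4308 for the crossed pairing, or 2.15 and 2.19 times higher. The share of regions found in both of 2 libraries (Jaccard index) was 0.510 for the SUV39H2 ASO pair, 0.431 for the Ctr ASO pair, and 0.430 to 0.441 between groups. Within batch 1, 60106 regions were called only with SUV39H2 ASO and 57927 only with Ctr ASO, a ratio of 1.04. Within batch 2, whose SUV39H2 ASO list was the shorter, these were 40700 and 63991, a ratio of 0.64. With lists cut to the 124217 strongest peaks each, they were 39388 and 37704 in batch 1 and 43429 and 43191 in batch 2, though lists of equal length hold such counts close to each other. Gained and lost regions were 10798 and 5608 with lists of that length, a ratio of 1.93, and the ratio was 1.301, 1.06 and 0.99 with lists of 62108, 31054 and 15527 peaks.

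**Figure D1:**
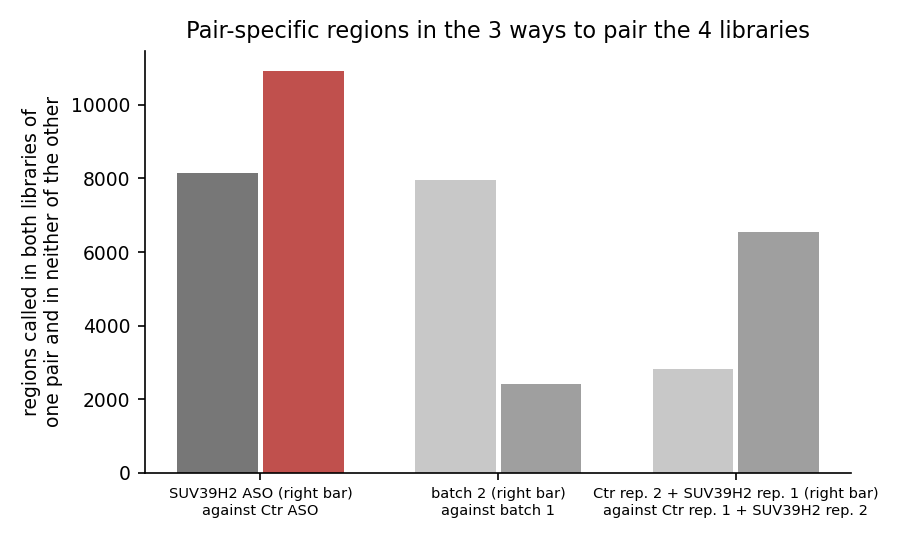
Number of regions called in both libraries of one pair and in neither library of the other (y axis), for the 3 ways to part the 4 libraries into pairs (x axis). Each bar is a single count without an error. The treatment split has 10926 gained and 8162 lost regions, the batch split 2423 and 7967, and the crossed split 6553 and 2832.

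At the ASO's target gene, a site inside the gene was lost and a site at its end was called throughout. SUV39H2 (chromosome 10:14878866-14904315, GRCh38) had a region at one of its ends, 14877872-14879329, that was called in all 4 libraries, with a fold of 10.6 and 10.4 in the Ctr ASO lists and of 14.01 and 13.2 in the SUV39H2 ASO lists. A further region of 695 bp inside the gene, 14896850-14897544, was called in both Ctr ASO libraries, at a fold of 7.80 and 8.51, and in neither SUV39H2 ASO library. This region also covers an end of DCLRE1C (14897359-14954432), which encodes the nuclease Artemis and overlaps SUV39H2. In the ranking within the Ctr ASO lists it stood at percentiles 72.4 and 76.5 of −log10 q, and 19 of all lost regions (0.233%) were as strong. Weaker peaks inside SUV39H2 were called in single libraries. SUV39H1, the paralog on chromosome X, had 2 regions, both called in all 4 libraries. Peak lists of accessible DNA measure neither SUV39H2 transcript nor its splicing.

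**Figure D2:**
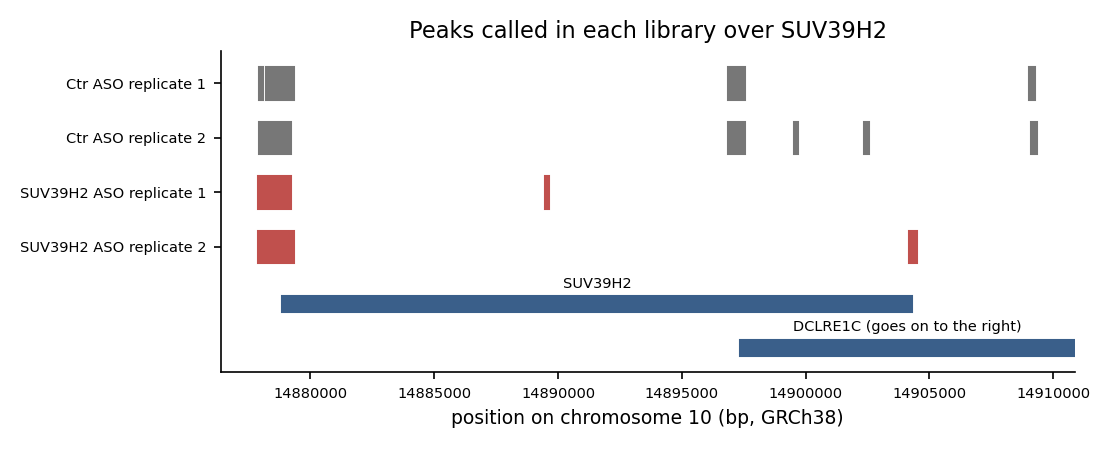
Peaks called in each library (boxes, one line per library) over SUV39H2 and part of DCLRE1C, against position on chromosome 10 in bp. The box at 14896850-14897544 is present in both Ctr ASO libraries and in neither SUV39H2 ASO library, and the box at 14877872-14879329 is present in all 4.

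Regions at the ends of protein-coding genes made up a larger share of gained than of lost regions when whole peaks were compared. A total of 835 gained and 429 lost regions lay within 1000 bp of a gene end, 7.64% of the gained, 5.26% of the lost and 19.0% of the regions called in all 4 libraries. This was a log2 odds of 0.58 ± 0.09 (SE; two-sided Fisher's exact test, adjusted p = 1.19e-10). Regions between genes went the other way, with 4921 gained and 3968 lost (log2 odds −0.21 ± 0.04, Fisher's exact adjusted p = 1.45e-06), and regions inside genes, 5170 gained and 3765 lost, did not pass (adjusted p = 0.104). No class passed in the batch split or the crossed split (0 of 3 classes by Fisher's exact test, and 0 at an unadjusted p under 0.05). With windows of 250 bp either side of the summits in place of whole peaks, 776 gained and 762 lost regions lay at gene ends and the direction turned (log2 odds −0.20, Fisher's exact adjusted p = 0.0158). With whole peaks it turned to −0.085 (Fisher's exact adjusted p = 0.241) without SUV39H2 ASO replicate 2.

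Among the 31054 strongest peaks of each library, gene ends ranked apart by treatment in both forms of the comparison, which was added after seeing the data. The 31054 strongest peaks of each library formed its top list, and regions in the top lists of both libraries of one group and of neither library of the other were compared. Of 2576 such regions of the SUV39H2 ASO 671 (26.0%) lay at gene ends, and of 2426 of the Ctr ASO 127 (5.23%) did, a log2 odds of 2.67 ± 0.15 (SE, Fisher's exact p = 2.69e-97). Nearly all were called in the other group as well, since 655 of the 671 and 126 of the 127 overlapped a peak in both full lists of the other group, so the difference is one of rank and not of sites called in one group only. With windows around summits it was 1.98 ± 0.12 (Fisher's exact p = 4.98e-70). Batch 1 alone gave 2.25 ± 0.10 and batch 2 alone 2.42 ± 0.09 with whole peaks, and leaving out 1 library at a time gave 2.25 to 2.72. With windows the batches gave 1.61 ± 0.08 and 1.85 ± 0.08, and leaving out 1 library at a time gave 1.51 to 2.07. The batch split gave 0.94 ± 0.32 and the crossed split −0.31 ± 0.38 with whole peaks, and 1.04 ± 0.28 and −0.40 ± 0.33 with windows around summits. With windows and 62108 peaks per library, however, the batch split gave 1.34 ± 0.21, more than the 0.48 ± 0.10 of the treatment, which fell to 0.040 ± 0.079 (Fisher's exact p = 0.621) without SUV39H2 ASO replicate 2. With windows and 124217 peaks the treatment turned to −0.27 ± 0.08 (Fisher's exact p = 0.000937), and to −0.99 without SUV39H2 ASO replicate 2. The batch split gave 0.85 ± 0.13 there, while whole peaks gave 0.79 ± 0.10 for the treatment at that length. With top lists of 15527 peaks, gene ends made up 48.0% of the regions of the SUV39H2 ASO and 6.39% of those of the Ctr ASO. These p-values count regions as units in 4 libraries and do not measure the spread between cultures.

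**Figure D3:**
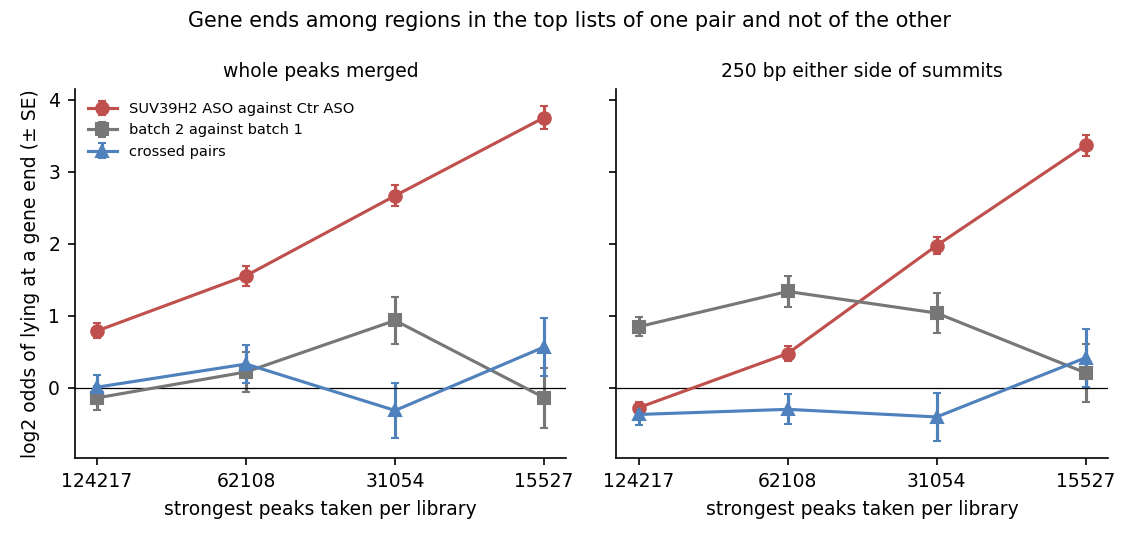
Log2 odds (y axis, with SE) that a region in the top lists of one pair and not of the other lay at a gene end, against the number of strongest peaks in each top list (x axis), for whole peaks on the left and windows around summits on the right. The treatment line reaches 3.75 and 3.37 at 15527 peaks, while the batch and crossed lines end at −0.14 and 0.57 on the left and 0.21 and 0.42 on the right. At 124217 peaks on the right the treatment line starts at −0.27, below the batch line at 0.85.

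The named regions were ranked by the weaker of their percentiles of −log10 q. After TUBD1 at percentile 87.0, the gained regions at gene ends lay at TNFRSF12A (chromosome 16:3021848-3022156), the receptor of the cytokine TWEAK, at percentile 85.4, and at SARS1 (chromosome 1:109214860-109215141), the cytosolic seryl-tRNA synthetase, at 85.2. They went on with KRT80, a keratin, at 82.3, a further TUBD1 region at 80.2, RASSF5 at 79.6, CEBPB, a leucine zipper transcription factor, at 77.8, RALA, a small GTPase, at 76.6, ACCSL at 75.3 and KMT2E at 75.1. Of any class, the strongest gained regions included chromosome 1:117826478-117826764, nearest to GDAP2, at 87.3 and chromosome 20:47274554-47274841, inside ZMYND8, at 86.1. The lost regions at gene ends lay at ACTB at percentile 74.1, DCLRE1C inside SUV39H2 at 72.4, TOM1L2 at 70.9, IFT43, of intraflagellar transport, at 67.3, TBC1D30 at 67.0, RPL7, a ribosomal protein gene, at 64.7, SMIM5 at 61.0, CACNG3 at 60.1, TSEN2 at 59.7 and CCDC116 at 59.6. Of any class, the strongest lost regions lay inside GSE1 (chromosome 16:85610057-85610348) at 85.2 and nearest to PARD6B at 82.9, CCDC200 at 80.98 and CABLES1 at 77.9. The fifth, chromosome 2:41142554-41143151, at 76.9, had no protein-coding gene within 100 kb.

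Gained regions outnumbered lost ones at p53 target genes, the only list of 42 that passed, with 35 gained and 7 lost regions (83.3% gained, 95% exact interval 68.6% to 93.0%, against 57.2% of all gained and lost regions). The log2 odds was 1.83 ± 0.58 (SE; two-sided Fisher's exact test, adjusted p = 0.0195). Of the 32 genes of the list, 16 had gained regions only, 2 had lost regions only and 2 had both. BTG2, an antiproliferative gene, had 3 gained regions, and CCNG1, FDXR, MDM2, PLK2, PHLDA3, SPATA18 and the death receptor genes TNFRSF10A and TNFRSF10B had 2 each. CDKN1A, which encodes the CDK inhibitor p21, FAS, BBC3, AEN, XPC, ZMAT3 and PLK3 had 1 each. PPM1D, a phosphatase that acts on p53, had 7 gained and 4 lost regions, PMAIP1 had 2 and 1, and DDB2 and PERP had 1 lost region each. MDM2 encodes the ligase that degrades p53, and its gained regions lay inside the gene at chromosome 12:68814592-68814850 and 12:68815473-68815753. Within the batches the list also passed, with a log2 odds of 0.82 in a Cochran-Mantel-Haenszel test. It passed with regions assigned within 20 kb of a gene (2.44, 32 gained and 4 lost, Fisher's exact adjusted p = 0.00254). By nearest gene end it passed too (1.87, 41 and 8, Fisher's exact adjusted p = 0.00511). The log2 odds was 1.62 without Ctr ASO replicate 1 (41 and 37) and 1.58 without Ctr ASO replicate 2 (43 and 49). The log2 odds stayed at 1.64 with 50% coverage (34 gained and 7 lost, Fisher's exact adjusted p = 0.0883) and was 1.15 with windows around summits (29 and 11, adjusted p = 0.396), past the threshold in neither. The call also ended with the same number of strongest peaks from each library (log2 odds 0.99, Fisher's exact adjusted p = 0.765), with a −log10 q of at least 5 (0.35, 31 gained and 8 lost) or 10 (2.77, 17 and 0), with at least 5 only where called (0.52, 26 and 5), with each gene counted once, which left 18 gained and 2 lost genes (2.198, adjusted p = 0.401), without SUV39H2 ASO replicate 1 (0.69) and without SUV39H2 ASO replicate 2 (0.84).

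**Figure D4:**
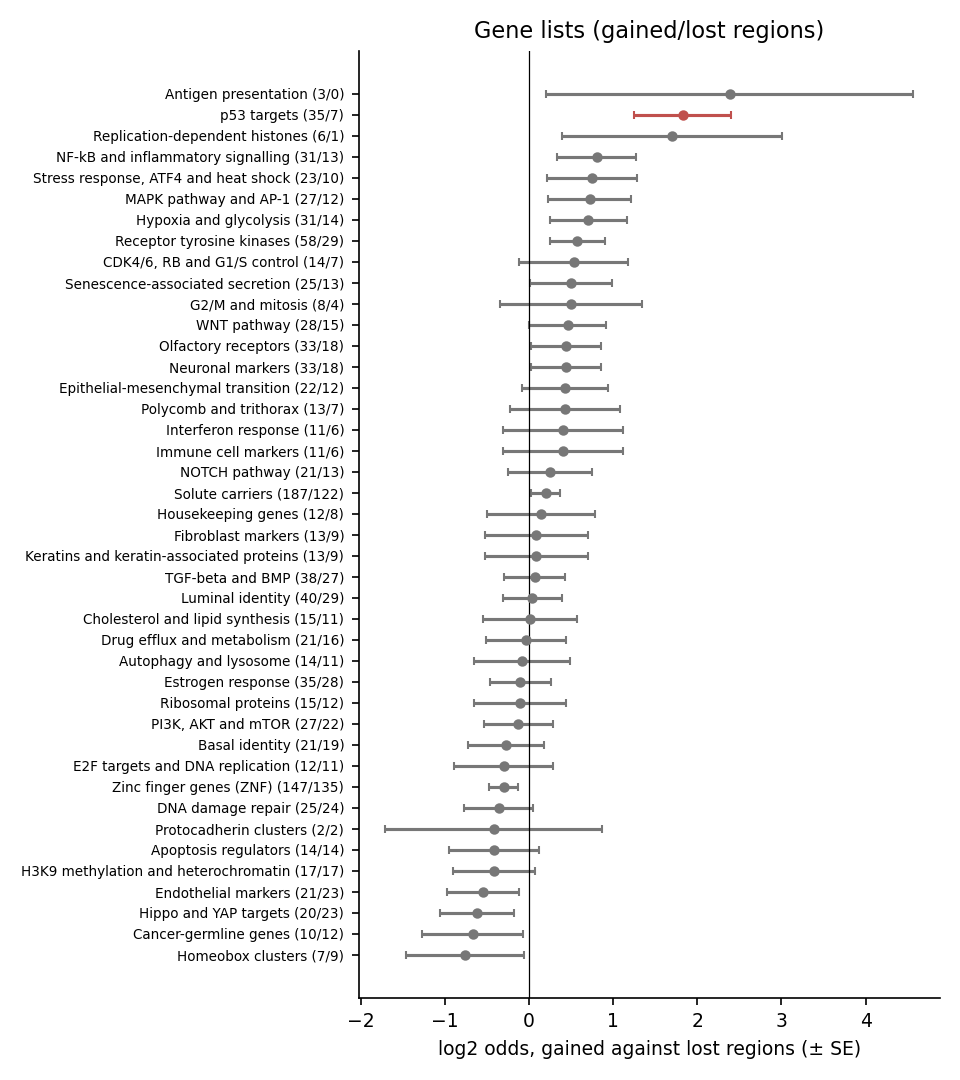
Log2 odds with SE (x axis) of gained against lost regions for each of 42 gene lists (y axis, with the gained and lost regions in brackets). The list that passed, p53 targets, is in red at 1.83, and Antigen presentation at 2.39 rests on 3 gained regions.

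Lists tied to the target and to the disease setting had gained and lost regions in shares that did not pass, each with an adjusted p above 0.8 by Fisher's exact test. The list of H3K9 methylation and heterochromatin had 17 gained and 17 lost regions, with KDM4B, an H3K9 demethylase gene, at 4 and 2, MECOM at 2 and 4, ATF7IP at 2 and 0, TRIM28 at 2 and 1, DNMT3A at 1 and 2 and EHMT1, which encodes an H3K9 methyltransferase, at 0 and 2. Zinc finger genes, many of which carry H3K9 trimethylation, had 147 gained and 135 lost regions (log2 odds −0.30 ± 0.17, Fisher's exact adjusted p = 0.808), with ZNF217 at 4 and 7, ZNF385B at 4 and 1, ZNF704 and ZNF706 at 3 and 3, ZNF804B at 3 and 6, and ZNF521 and ZNF572 at 2 and 5. Under the replicate block this list passed, at a log2 odds of −0.20. The CDK4/6, RB and G1/S list had 14 gained and 7 lost regions. Its member MYC had 4 gained regions and none lost, CCND3 had 2 and 0, CDK6 had 1 and 2, and CCNE1, CCNE2 and RB1 had 1 lost region each. Estrogen response genes had 35 and 28, with RAB31 at 3 and 1, ELOVL2 at 2 and 0, IGFBP5 at 2 and 1, CA12 at 1 and 2, ELOVL5 and HSPB8 at 0 and 2 and BCL2, an inhibitor of apoptosis, at 0 and 8. Interferon response genes had 11 and 6, with IFNB1 at 3 and 0, SAMD9 at 3 and 1, ISG20 at 2 and 0, ADAR at 1 and 0, IRF1 at 1 and 1, ZBP1 at 0 and 2, and PARP9 and RIGI at 1 lost region each.

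Under the replicate block 5 lists passed in place of 1. Beside the p53 and zinc finger lists these were NF-kB and inflammatory signalling (31 gained and 13 lost, block log2 odds 0.62), MAPK pathway and AP-1 (27 and 12, block log2 odds 0.51) and replication-dependent histones (6 and 1, block log2 odds 1.18). The block test counts a region in each batch where it differs, so its strata share regions. In the batch split and the crossed split, 0 of 42 lists passed by Fisher's exact test, and 0 had an unadjusted p under 0.05.

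None of the other lists passed under either test. Among signalling lists, receptor tyrosine kinases had 58 gained and 29 lost regions, the WNT pathway 28 and 15, the NOTCH pathway 21 and 13, TGF-beta and BMP 38 and 27, PI3K, AKT and mTOR 27 and 22, and Hippo and YAP targets 20 and 23. Among cell state lists, luminal identity had 40 and 29, basal identity 21 and 19, epithelial-mesenchymal transition 22 and 12, senescence-associated secretion 25 and 13, hypoxia and glycolysis 31 and 14, and the list of stress response, ATF4 and heat shock 23 and 10. Among cell cycle and genome lists, E2F targets and DNA replication had 12 and 11, G2/M and mitosis 8 and 4, DNA damage repair 25 and 24, apoptosis regulators 14 and 14, and polycomb and trithorax 13 and 7. Among metabolic lists, cholesterol and lipid synthesis had 15 and 11, autophagy and lysosome 14 and 11, drug efflux and metabolism 21 and 16, and solute carriers 187 and 122. Antigen presentation had 3 and 0, cancer-germline genes 10 and 12, homeobox clusters 7 and 9, protocadherin clusters 2 and 2, keratins and keratin-associated proteins 13 and 9, olfactory receptors 33 and 18, ribosomal proteins 15 and 12 and housekeeping genes 12 and 8. Markers of lineages not in the culture had 33 and 18 for neurons, 13 and 9 for fibroblasts, 21 and 23 for endothelium and 11 and 6 for immune cells.

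Of 21 genes of the fixed panel, 18 had a region within 1000 bp of an annotated end that was called in all 4 libraries. These included the luminal regulators GATA3 and FOXA1, the estrogen-responsive genes TFF1, GREB1 and PGR, and the cell cycle genes CCND1, CCNE1, CCNE2, CDK2, CDK4, CDKN2A, RB1, E2F1 and MYC, with FGFR1, BCL2, SUV39H1 and SUV39H2. The exceptions were ESR1, CDK6 and CDKN1A. ESR1, the estrogen receptor gene, had 88 assigned regions, of which 23 were called in all 4 libraries, 5 were gained and 6 lost. GATA3 had 1 gained and 4 lost regions, and CCND1, which encodes cyclin D1, had none of either kind among 24 regions. CDKN2A, FOXA1, TFF1, E2F1, CDK2 and CDK4 had none of either kind. FGFR1 and PGR had 1 lost region each, and GREB1 had 1 of each kind.

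A total of 26 genes had at least 5 gained and no lost regions, and 16 had at least 5 lost and no gained regions. The former were led by ANK3 and ANKS1B with 7 gained regions each and by BCL6, a transcriptional repressor, CAMTA1, KAZN, KIF16B and SARAF with 6 each. The latter were led by BMP7, a bone morphogenetic protein gene, with 9 lost regions, BCL2 and RABGAP1L with 8 each, and TRAPPC9 and XXYLT1 with 7 each. At BMP7, with 118 assigned regions, batch 1 had 31 regions called only with Ctr ASO and 11 only with SUV39H2 ASO, and batch 2 had 29 and 7. At BCL2, with 61 assigned regions, these were 17 and 13 in batch 1 and 21 and 4 in batch 2. The weaker percentiles of the 8 lost BCL2 regions ran from 0.83 to 52.2. In an exact binomial test per gene, added after seeing the data, 0 of 307 genes with at least 6 gained or lost regions passed, 26 (8.47%) had an unadjusted p under 0.05, and the lowest adjusted p was 0.114. The batch split gave 8 of 98 genes (8.16%) under 0.05, a similar share, and the crossed split 3 of 98 (3.06%), with 0 passing in either.

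The share of gained regions differed between chromosomes, and 10 of 23 passed (Fisher's exact test, Benjamini-Hochberg). Chromosome X had 220 gained and 102 lost regions (68.3% gained, 95% exact interval 62.9% to 73.4%), chromosome 6 had 543 and 256 (68.0%, 64.6% to 71.2%), chromosome 11 had 429 and 248 (63.4%), chromosome 9 had 428 and 260 (62.2%) and chromosome 5 had 641 and 415 (60.7%). The share was lower on chromosome 7 with 678 and 675 (50.1%), chromosome 8 with 641 and 642 (49.96%), chromosome 18 with 249 and 244 (50.5%), chromosome 20 with 354 and 343 (50.8%) and chromosome 21 with 88 and 94 (48.4%). Under the replicate block 6 passed, namely 1, 6, 7, 11, 21 and X, and the batch split also gave 5 passing chromosomes. With top lists of 62108 peaks, in which presence and absence again refer to rank, 2 chromosomes passed, and X and 7 changed direction there. Without SUV39H2 ASO replicate 1, 4 passed and the log2 odds of X turned from 0.70 to −0.23 (Fisher's exact adjusted p = 0.0933). The call of X also ended with the same number of strongest peaks (0.38, Fisher's exact adjusted p = 0.0836) and with a −log10 q of at least 5 (0.11, adjusted p = 0.751).

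**Figure D5:**
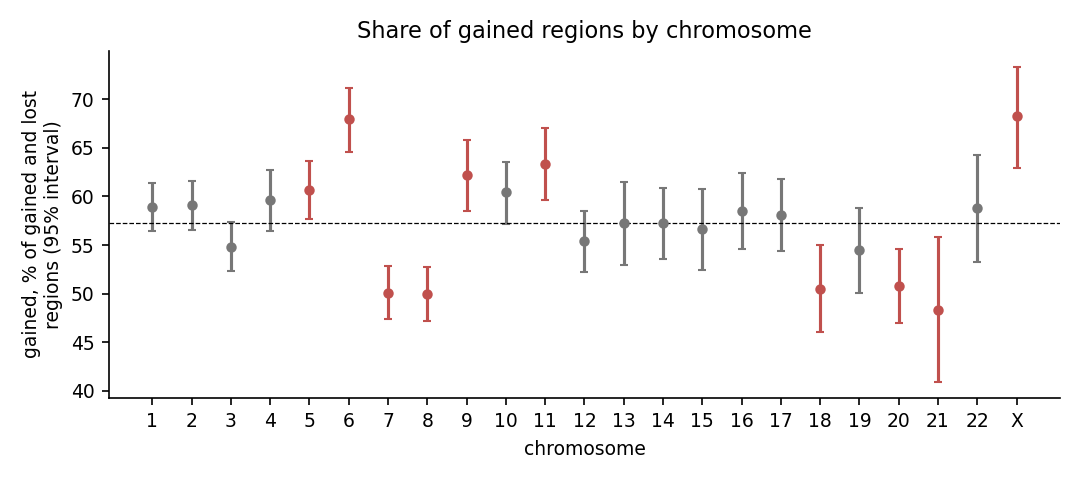
Gained regions as a percent of gained and lost regions (y axis, with 95% exact binomial intervals) for each chromosome (x axis), with those that passed in red and the genome-wide 57.2% as a dashed line. Chromosomes 6 and X lie at 68.0% and 68.3%, and chromosomes 7, 8 and 20 between 49.96% and 50.8%.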

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

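The tests of classes, chromosomes and lists at stricter thresholds, at 62108 or fewer strongest peaks, with 50% coverage and with windows around summits, the counts at 31054 peaks, and the list test by nearest gene end were chosen only after the data were seen. Where a value changed, the cause was not tested unless the setting itself shows it. With a −log10 q of at least 5, peaks per library turned from −11902 to 6918.5 (SUV39H2 ASO minus Ctr ASO). There 10237 regions were gained and 3514 lost, 879 and 171 at gene ends (log2 odds 0.87, Fisher's exact adjusted p = 3.12e-13), and 0 gene lists passed. With at least 10, the difference was 11843, and 8032 regions were gained and 1567 lost. At gene ends these were 892 and 64 (log2 odds 1.54, Fisher's exact adjusted p = 4.85e-20). At this threshold 0 lists and 1 chromosome passed, and the log2 odds of chromosomes 7 and X turned to 0.17 and −0.25. With at least 5 where called and absence at the authors' threshold elsewhere, 7491 regions were gained and 2222 lost, 641 and 120 at gene ends. The log2 odds of gene ends was 0.71, and 0 lists and 4 chromosomes passed. With the same number of strongest peaks per library, 864 gene-end regions were gained and 268 lost, and 0 lists passed. In the settings with fewer strongest peaks, gained and lost refer to the lists as cut. At 62108 peaks, 4656 regions were gained and 3578 lost, 539 and 152 at gene ends, 2 chromosomes and 0 lists passed, and chromosomes 7 and X turned to 0.11 and −0.38. At 31054 peaks, 2576 were gained and 2426 lost, with 127 lost at gene ends, 3 chromosomes and 0 lists passed, and chromosomes 20 and X turned to 0.13 and −0.47. All of these settings keep fewer peaks by construction. Lists passed in 0 cases with 50% coverage, with windows around summits and with each gene counted once, where the log2 odds of the p53 list was 1.64, 1.15 and 2.198 against 1.83. Windows around summits gave 762 lost gene-end regions and turned the log2 odds of gene ends to −0.20. Within 500 bp of a gene end 466 regions were gained, and within 2000 bp 661 were lost. Leaving out 1 library at a time asks for fewer calls, so gained regions ran from 15724 to 49111, lost from 10243 to 53552 (lost regions outnumbered gained ones without either Ctr ASO library, with 17855 gained and 49498 lost or 15724 and 53552), gained gene-end regions from 1216 to 2432 and lost ones from 536 to 2097. Passing lists then ran from 0 to 5 and passing chromosomes from 4 to 15, the log2 odds of gene ends ran from −0.085 (without SUV39H2 ASO replicate 2) to 1.05 and that of chromosome X from −0.23 (without SUV39H2 ASO replicate 1) to 1.37. The replicate block gave 5 lists and 6 chromosomes in place of 1 and 10, and it changed no class call. Under this pairing, batch 1 alone gave 60106 regions only with SUV39H2 ASO and 57927 only with Ctr ASO (3050 and 2290 at gene ends), and batch 2 alone 40700 and 63991 (2167 and 2747), counts of 1 library against 1. Library similarity within minus between groups was 0.0369, and 0.0469 with equal numbers of peaks or 0.0377 in base pairs. The first value rests on the SUV39H2 ASO pair (Jaccard index 0.510), since the Ctr ASO pair (0.431) lay within the between-group range of 0.430 to 0.441. Over all settings, 56 counts or differences kept within the limits set. Among tests of single classes, chromosomes or lists, 161 kept their direction and call, while 33 lost a call and 6 gained one. The log2 odds of lists that changed sign passed in neither setting. For zinc finger genes it turned to 0.0024 and 0.032 with a −log10 q of at least 5 throughout or only where called, 0.022, 0.040 and 0.66 with equal numbers of strongest peaks, from the most to the fewest, and 0.099 without SUV39H2 ASO replicate 1 (−0.37 to 0.099 over libraries left out). For H3K9 methylation it turned to 0.18 with the same number of strongest peaks. For MAPK and AP-1 it turned to −0.11 with at least 5 only where called, and to −0.38 and −0.25 at 62108 and 31054 peaks. For interferon response it turned to −0.16 with at least 10, −0.17 with at least 5 only where called, −0.061 without Ctr ASO replicate 2 (−0.061 to 0.75 over libraries left out), −0.18 within 20 kb and −0.043 with each gene counted once. For CDK4/6 it turned to −0.090 at 62108 peaks, −0.076 with windows around summits, −0.42 and −0.017 without SUV39H2 ASO replicate 1 or 2 (−0.42 to 0.86 over libraries left out), and −0.067 with each gene counted once. For estrogen response it turned to 0.033 and 0.23 without Ctr ASO replicate 1 or 2 (−0.56 to 0.23 over libraries left out), 0.065 within 20 kb and 0.35 with each gene counted once, and for NF-kB to −0.036 without SUV39H2 ASO replicate 2 (−0.036 to 1.21 over libraries left out). Tests of motifs, GC content and repeats and their alternatives were not run, for want of a genome sequence. A depth of 55478293 to 65661691 tags with 143515 regions called in 1 library limits what absence of a call shows.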

Other observations

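The tests of explanations in this part and the tests of 5 Mb stretches were chosen after the results were seen, while the counts of gained and lost regions, the p53 list test with all peaks, and these counts in lists of 124217 or 62108 peaks had been fixed before. Stretches of 5 Mb with at least 20 gained or lost regions were compared with the genome-wide share of gained regions by exact binomial tests, and 17 of 402 passed, 5 with a higher and 12 with a lower share, against 0 of 220 in the batch split and 0 of 186 in the crossed split. Gained regions led at chromosome 1 from 25 to 30 Mb with 37 gained and 6 lost (exact binomial adjusted p = 0.0102), chromosome 8 from 20 to 25 Mb, which holds TNFRSF10A and TNFRSF10B, with 29 and 4 (adjusted p = 0.0193), chromosome 13 from 105 to 110 Mb with 22 and 2 (adjusted p = 0.0193) and chromosome 11 from 10 to 15 Mb with 24 and 3 (adjusted p = 0.0287). Lost regions led at chromosome 3 from 165 to 170 Mb, which holds MECOM, with 23 and 49 (exact binomial adjusted p = 0.00796), chromosome 3 from 195 to 200 Mb, which holds XXYLT1, with 17 and 40 (adjusted p = 0.00796), and chromosome 20 from 55 to 60 Mb, which holds BMP7, with 25 and 45 (adjusted p = 0.0193).

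Gene ends ranked higher with the SUV39H2 ASO, at 26.0% of the regions only in its top lists of 31054 peaks against 5.23% of those only in the Ctr ASO top lists, and 655 of these 671 and 126 of these 127 gene-end regions were called in both full lists of the other group, so they are shifts in rank. How overlapping peaks were merged into regions does not alone account for it, since windows around summits kept a log2 odds of 1.98 ± 0.12 (SE). The top lists were ranked by the q of whole peaks before windows were set, so peaks split differently by the caller stay open. A single library does not account for it at that length. The lowest value over libraries left out and single batches, in either form, was 1.51 ± 0.10, with windows and without SUV39H2 ASO replicate 2. With windows, that library left out gave 0.040 ± 0.079 at 62108 peaks and −0.99 at 124217. All 4 libraries gave −0.27 ± 0.08 at 124217 peaks with windows, so the difference does not extend to lists of that length. With all peaks, windows around summits likewise gave −0.20 ± 0.07, so how peaks were merged may be the whole of the excess there. A higher signal over background in the SUV39H2 ASO libraries, whose lowest median fold lay 0.93 above the highest of the Ctr ASO libraries, cannot be told apart from an effect of the ASO, because it goes with the group in both batches. A treatment effect on the relative signal of promoters or other gene ends stays open as untested.

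More regions were gained than lost, 10926 against 8162, but not in every setting: batch 2 alone, with a shorter SUV39H2 ASO list, had 40700 only with SUV39H2 ASO against 63991 only with Ctr ASO, and 17855 against 49498 or 15724 against 53552 were left without Ctr ASO replicate 1 or 2, where a lost region needs only 1 call. Whether peaks near the calling threshold account for this stays open. Regions with a weaker percentile of q within each list of at least 50 and no call in the other group were 1755 gained and 662 lost. That was a ratio of 2.65 (exact 95% counting interval 2.42 to 2.90) against 2.09 at a percentile of at least 25 and 1.34 with all. Absence was still judged at the authors' cutoff, so sites just below it in the other group were not set apart. The same percentile was also a stricter q in the SUV39H2 ASO lists. There 53.7% and 54.8% of peaks had a −log10 q of at least 10, against 42.0% and 42.2% in the Ctr ASO lists. With a −log10 q of at least 5 in all lists, 10237 regions were gained and 3514 lost, and with at least 10 these were 8032 and 1567. With lists of equal length the ratio was 1.93 at 124217 peaks, where the SUV39H2 ASO pair had a Jaccard index of 0.575 and the Ctr ASO pair 0.502. It fell to 1.06 at 31054 peaks and 0.99 at 15527. In lists of equal length a region ranked up displaces another, which draws this ratio towards 1 where the lists share most regions. At 31054 peaks the Jaccard index was 0.829 for the SUV39H2 ASO pair and 0.806 for the Ctr ASO pair. These ratios therefore cannot decide whether the strongest peaks had such an excess. Presence in these lists refers to rank. At 31054 peaks, 2409 of the 2576 regions of the SUV39H2 ASO and 2410 of the 2426 of the Ctr ASO overlapped a peak in both full lists of the other group. A higher signal over background in the SUV39H2 ASO libraries, whose lowest median fold lay 0.93 above the highest of the Ctr ASO libraries, raises q at a given site and cannot be told apart from an effect of the ASO, because it goes with the group in both batches. An opening of more sites than were closed by the treatment stays open as untested.

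Gained regions outnumbered lost ones in the p53 list. Membership of its regions in the gene-end class does not account for this, since within genomic classes the log2 odds was 1.88 ± 0.60 (SE). That class held 4 gained and 1 lost of its regions, against 18 and 1 inside genes and 13 and 5 between genes. Regions a little farther from a gene end fell in the other classes, so closeness to gene ends beyond that class was not tested and stays open. Whether weak peaks near the calling threshold set the list apart stays open, since with a −log10 q of at least 5 the log2 odds went from 1.83 ± 0.58 to 0.35 ± 0.56, while the list still had 31 gained and 8 lost regions (79.5% gained) and the share of gained among all gained and lost regions rose from 57.2% to 74.4%, and at 10 the list had 17 and 0 (2.77 ± 2.07). Activation of p53 by the ASO is a hypothesis that these peak lists did not test.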
